A study of Mus musculus with 31 samples.

How the data were processed

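Lung miRNAs were measured in female BALB/c mice, an inbred strain, after 4, 6, 8 or 12 weeks of cigarette smoke or room air. Per the labels, total RNA was extracted with TRIzol, labelled at its 3' end with Cy3 and hybridised to 1-colour Agilent mouse miRNA arrays. The 31 arrays form 8 groups, smoke and control at each duration, with 4 arrays per group and 3 in the 12 weeks smoke group. Groups and replicate numbers were read from the sample titles. Whether the arrays of a group come from separate animals is not given in the sources used here, so every p-value measures only the spread between these samples, which may be technical.

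The arrays were scanned on 4 slides of 8 positions. Every slide holds both groups of every duration, except that slide 4 has no 12 weeks smoke array, so slide and group are separate. Smoke samples always lie in the first line of positions of a slide and control samples in the second, and the column is the duration, so an effect of array position cannot be told apart from an effect of smoke or duration. Mouse age and cigarette dose are not given in the sources used here.

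The spot values are scanner intensity, background-subtracted and detrended by Feature Extraction 10.7.3.1 and not normalized between arrays, per the file headers. The quality marks of each spot (outlier, saturated, above background) were also set by that software, per the file headers. The deposited series table holds log2 values for 650 entries that were normalized between arrays by the authors with a method not given in the sources used here. Its array medians lie between 2.71 and 2.85, and its correlation with the scaled scanner values is 0.981 to 0.985 per array, from which its scale and direction were taken.

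Each array has 13715 spots, of which 13000 are not controls, for 1857 probes of 650 miRNAs (611 of mouse and 39 of herpesviruses). From the processed signal, spots marked as outliers (297 to 655 per array) and control spots were left out, and the remaining spots of a probe were averaged. A probe counts as detected on an array when 50% of its spots are above background. Each array was divided by its 75th percentile over the 385 probes detected on all 31 arrays. Signals under a floor, the median over arrays of the lowest scaled signal among detected probes (log2 -6.74), were set to it, and log2 was taken. The brightest probe stood for each miRNA: 359 miRNAs have 2 probes, 274 have 4, 13 have 3 and 4 have 1. A miRNA was tested if detected on 75% of the arrays of any group, which left 273 (270 mouse, 3 viral), of which 207 were detected on every array and 194 have all their probes changing with the same sign in the averaged comparison.

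Differences were estimated in R 4.3.3 with limma 3.58.1, with 1 mean per group and moderated variances on 23 residual degrees of freedom. The 7 results are smoke minus control at each duration, their average with equal weight per duration, a moderated F test for a smoke effect that differs between durations, a moderated F test for differences between durations among control mice, and a list test of the averaged comparison. Adjusted p-values are those of Benjamini and Hochberg over the 273 miRNAs of a comparison, and a miRNA is said to have changed at an adjusted p of 0.05 or less. Values are log2 differences with the model's standard error (SE). Where the lower group lies under the floor, the fold change is a lower bound: the higher group's mean over the mean of, per array, the larger of the lowest signal above background and the probe's own signal.

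For the lists, 19 groups of miRNAs were fixed from general knowledge, and the 15 with at least 3 tested members were compared with all other miRNAs by camera of limma, with the preset correlation of 0.01 and again with the correlation estimated from the members. A self-contained test, fry of limma, asks instead whether the members changed at all, without comparison to other miRNAs. The lists are inflammation-responsive, leukocyte, epithelial, multiciliated, smooth muscle and mesenchymal, striated muscle, the miR-17 clusters, let-7, miR-30, miR-29, the miR-23-24-27 clusters, miR-15-16, p53 and DNA damage, the imprinted Dlk1-Dio3 region and viral controls. Erythroid, endothelial, liver and hypoxia lists have fewer than 3 tested members and were only described. Overlapping lists are few: inflammation-responsive and leukocyte share 2 members, and multiciliated and p53 share 4.

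Named miRNAs are, for each smoke comparison, up to 15 of the largest rises and 10 of the largest falls that passed, the list members that passed (or up to 4 examples where none did) and miR-21. For the 2 F tests the 10 miRNAs with the lowest p are named. The groups, comparisons, lists, naming rule and most alternatives were made before the data were examined. The alternatives are other scalings (75th percentile of all probes, quantile, none), the scanner's summed signal per miRNA, the mean of all probes, no detection filter, detection on every array, a floor 4 times higher, the deposited series table, replicate number or slide as a block, a variance trend with robust moderation, each comparison fitted on its own groups, the estimated correlation for lists, and every array left out in turn. A planned background correction (normexp on mean spot signal) was not run because that column is absent from the files used here; normexp with an offset of 50 on the median signal took its place. That alternative, 2 alternatives without chosen sets of arrays and 2 with a covariate were added after the data were seen.

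Recovery was tested on simulated values with planted changes in 60 of the 273 miRNAs over 20 runs. Each miRNA was drawn from a normal distribution with its own mean and residual spread, independently of the others. The runs lack the variation that miRNAs share on the real arrays, so the shares below may not hold there. At 4 weeks 71.0% of changes of 0.5 log2 were recovered, 95.8% of 1 log2 and 99.5% of 2 log2, with 4.15% false calls. With the 3 smoke arrays of 12 weeks the shares were 62.8%, 94.8% and 99.5% with 4.86% false calls, and in the averaged comparison 95.2%, 99.5% and 100% with 4.15%. A planted list shift of 0.5 log2 was called in 20 of 20 runs, with 5 calls of other lists. Where a correlation across arrays has a p-value, it is from random permutations of the arrays within their groups. No sample was left out of the principal comparisons.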

Results

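The largest change in lungs of smoke-exposed mice was in miR-135b-5p, a miRNA that responds to interleukin-1 receptor signalling in mouse lung, which rose by 4.36 ± 0.08 log2 (SE; 15 smoke and 16 control arrays, limma adjusted p 2.53e-25) averaged over the 4 durations. miR-146b-5p, which is induced through NF-kB and targets Traf6 and Irak1, rose by 1.24 ± 0.04 log2 (2.36-fold, 1.51e-19), and miR-21-5p, a miRNA of inflammation and tissue remodelling, by 1.20 ± 0.05 log2 (2.29-fold, 1.32e-17). miR-132-3p, whose gene is regulated by CREB, rose by 0.88 ± 0.09 log2 (1.84-fold, 1.41e-08). These 4 miRNAs were higher on each of the 15 smoke arrays than on any control array. No other miRNA passed at all 4 durations. The control signal of miR-135b-5p lies at the floor on all 16 arrays, so its difference is measured against the floor. These control values have no spread, so its SE and p-values rest on the spread of the smoke arrays alone. With the floor 4 times higher it is 2.36 log2 averaged and 1.95, 2.41, 2.10 and 2.98 log2 at 4, 6, 8 and 12 weeks, still past the test. miR-132-3p depends on the floor: with the higher one it is at 0.017 log2 averaged (limma adjusted p 0.65) and at 0.069 at 4 weeks, neither of which passes. After a normexp background correction it is at 0.12 log2 averaged and -0.72 at 4 weeks, neither past the test, where the medians of all miRNAs are at -0.14 and -0.76 log2. With the normexp correction miR-135b-5p is at 2.24 log2 averaged (1.29e-06) but at 0.90 at 4 weeks, where it does not pass (0.147).

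Over the 207 miRNAs detected on every array the leading component carried 47.5% of the variance and the second 17.9%. Smoke and control arrays separated on the second component, where the lowest smoke array lies at 0.20 and the highest control array at -0.30.

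**Figure D1:**
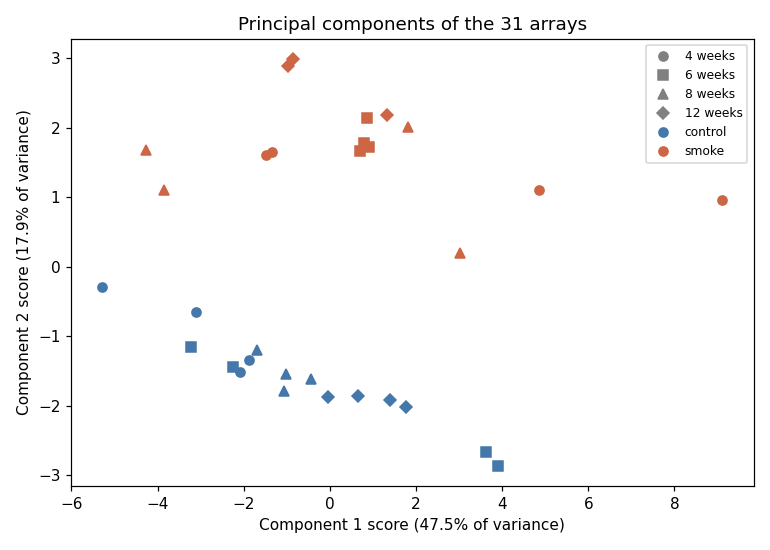
Each point is 1 of 31 arrays, placed by its scores on component 1 (47.5% of variance, horizontal) and component 2 (17.9%, vertical) of the log2 values, with colour for smoke or control and shape for duration. All smoke arrays lie at 0.20 or above on component 2 and all control arrays at -0.30 or below.

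Averaged over the durations, 76 of 273 miRNAs changed, 43 higher and 33 lower, while 109 had an unadjusted p under 0.05 and the median over all miRNAs was -0.0048 log2. With no scaling between arrays the split was 8 higher and 21 lower, and the median moved to -0.15 log2. Scaled by all probes it was 50 and 29. The balance also turns with quantile scaling (47 higher, 53 lower), the scanner's sum per miRNA (34 and 76), the deposited series table (46 and 66), without smoke arrays 2 and 3 of 4 weeks (47 and 53) and with the component score (65 and 78) or the 75th percentile (50 and 63) as a covariate. Beside the 4 miRNAs above, miR-34a-5p, a p53 target, rose by 0.67 ± 0.08 log2, and miR-449a-5p, a miRNA of multiciliated cells that shares its seed with miR-34a-5p, by 0.67 ± 0.09 log2 (limma adjusted p 4.96e-06). miR-34a-5p was above every control array on 14 of 15 smoke arrays and miR-449a-5p on 10 of 15. miR-31-3p rose by 0.42 ± 0.03 log2 and miR-31-5p by 0.41 ± 0.05 log2, from the 2 arms of 1 precursor. Further rises were those of miR-551b-3p (0.61 ± 0.13 log2), miR-135a-1-3p (0.59), miR-689_v15.0 (0.58) and miR-672-5p (0.56). miR-155-5p of activated leukocytes rose by 0.54 ± 0.11 log2, beside miR-139-3p (0.44), miR-1897-5p (0.44) and miR-146a-5p (0.43 ± 0.08). miR-20a-5p (0.14 log2) and miR-199a-3p (0.13) passed as small rises that turn to -0.0095 and -0.02 log2 with no scaling, both above that median of -0.15. With a normexp background correction miR-31-3p (-0.041 log2), miR-139-3p (-0.059), miR-1897-5p (-0.046), miR-141-5p (-0.091), miR-182-5p (-0.10) and miR-194-5p (-0.022) turn negative in the averaged comparison without passing, all above the median of all miRNAs, which it puts at -0.14 log2. It also ends the calls of miR-449a-5p (0.38 log2), miR-551b-3p (0.0021), miR-135a-1-3p (0.0055), miR-689_v15.0 (0.21), miR-672-5p (0.075), miR-155-5p (0.16) and miR-31-5p (0.14). In all it ends or turns 34 of 45 named calls of this comparison (28 ended, 6 turned) and leaves 12 changed miRNAs.

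Among the averaged falls the largest was miR-193-3p, at -0.81 ± 0.18 log2 (15 and 16 arrays, limma adjusted p 0.00125), followed by miR-32-5p at -0.76 ± 0.22. Both arms of miR-142, a precursor of haematopoietic cells, fell: miR-142-5p by 0.65 ± 0.13 log2 and miR-142-3p by 0.65 ± 0.17. miR-669f-3p (-0.53 ± 0.06 log2), miR-467d-3p (-0.45) and miR-466b-3p (-0.42) fell, all from the intron of Sfmbt2. The minor arms miR-24-1-5p (-0.49 ± 0.09 log2) and miR-24-2-5p (-0.43 ± 0.10) fell, while their shared major arm miR-24-3p was at 0.03 log2 (adjusted p 0.718). miR-455-3p fell by 0.45 log2, miR-30e-5p by 0.40 and miR-199b-5p by 0.37. miR-497-5p and miR-195-5p, 2 products of 1 cluster, fell by 0.29 ± 0.04 and 0.20 ± 0.05 log2, and miR-126-3p, from an intron of the endothelial gene Egfl7, fell by 0.13 log2 (0.00731). With the normexp correction miR-32-5p (adjusted p 0.0884), miR-669f-3p (0.354), miR-467d-3p (0.753), miR-466b-3p (0.753), miR-24-1-5p (0.175), miR-455-3p (0.198), miR-30e-5p (0.0827), miR-195-5p (0.334) and miR-126-3p (0.404) do not pass.

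The inflammation-responsive list was the only 1 of 15 called by camera with both correlations. Fry of limma, which makes no comparison with other miRNAs, called 5 lists. They are this one (fry adjusted p 6.25e-18), epithelial and p53 (1.565e-05 each), miR-30 (0.00694) and multiciliated (0.0132). Of the 9 tested inflammation-responsive members 8 rose and none fell, the same 8 when adjusted over the list alone, with a mean of 1.06 and a median of 0.54 log2 (camera of limma, adjusted p 3.38e-13; with the estimated correlation of 0.33 the adjusted p is 0.00284). The members that rose are miR-135b-5p, miR-146b-5p, miR-21-5p, miR-132-3p, miR-155-5p, miR-146a-5p, miR-31-3p and miR-31-5p, and miR-212-3p was at 0.08 log2. Within slides, the smoke minus control difference of the list mean, averaged over the durations on the slide, was 1.05, 1.06 and 0.96 log2 on the 3 slides with all 4 durations and 1.16 on the slide that lacks 12 weeks smoke. The list mean, these slide values and the list tests include miR-135b-5p, by far the largest rise, with its controls at the floor. They were not computed without it, and both arms of miR-31 count as separate members.

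**Figure D2:**
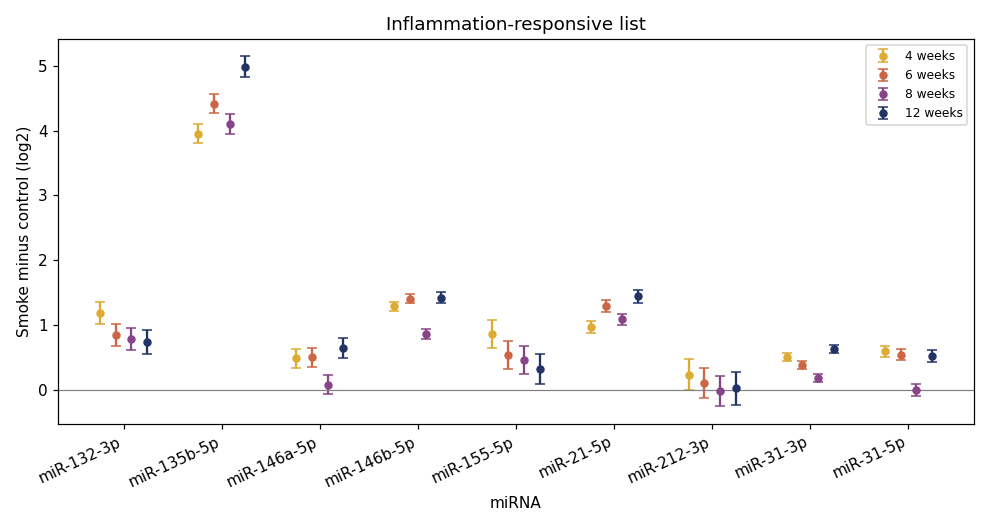
Smoke minus control difference (log2, vertical) of the 9 tested members of the inflammation-responsive list (horizontal), with 1 point per duration and bars for the SE. miR-135b-5p lies between 3.95 and 4.98 log2, and miR-146b-5p and miR-21-5p lie above 0.80 log2 at every duration.

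The leukocyte list has 8 tested members of which 3 rose, 2 fell and 3 did not pass, with 5 rises and 3 falls when adjusted over the list alone (camera of limma, adjusted p 0.776; with the estimated correlation the adjusted p is 0.913). miR-342-3p (0.32 ± 0.09 log2) rose in it with miR-155-5p and miR-146a-5p, against the falls of both arms of miR-142. Neither miR-223-3p of myeloid cells (0.34 ± 0.14, 0.0732) nor miR-150-5p of lymphocytes (-0.30 ± 0.12, 0.0691) passed. In the epithelial list 4 of 14 rose and none fell, also 4 when adjusted over the list alone (adjusted p 0.237; with the estimated correlation the adjusted p is 0.681). They are miR-183-5p (0.39 ± 0.06 log2), miR-182-5p (0.35 ± 0.06), miR-429-3p (0.27 ± 0.03) and miR-141-5p (0.26 ± 0.04), of which miR-429-3p belongs to the miR-200 family that represses Zeb1 and Zeb2. None of the 4 passes with the normexp correction, where miR-183-5p is at 0.053 log2 (0.899) and miR-429-3p at 0.20 (0.109). The p53 list had 3 rises among 7 members, also 3 when adjusted over the list alone (0.668; with the estimated correlation the adjusted p is 0.83). These are miR-34a-5p, miR-192-5p (0.28 ± 0.10 log2, adjusted p 0.0443) and miR-194-5p (0.23, 0.0246). miR-192-5p and miR-194-5p are also liver miRNAs, and both are highest on smoke array 3 of 12 weeks, where the liver miRNA miR-122-5p is 6.27 log2 above any other array; without that array they are at 0.14 log2 (0.00109) and 0.14 log2 (0.0126). miR-192-5p loses its call when any 1 of 22 of the 31 arrays is left out, and with slide as a block (0.0509).

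miR-449a-5p was the only rise among 5 multiciliated members, also 1 when adjusted over the list alone, and none fell (camera of limma, adjusted p 0.776; with the estimated correlation the adjusted p is 0.913). miR-34b-3p (-0.09 log2) and miR-34c-5p (-0.05) did not pass. In the miR-30 list miR-30e-5p and miR-30b-3p (-0.17 log2) fell and 6 of 8 did not pass, with 2 falls when adjusted over the list alone (0.237; with the estimated correlation 0.681). Of 8 miR-15-16 members miR-195-5p and miR-497-5p fell and 6 did not pass, with 2 falls when adjusted over the list alone (0.668). The miR-29 list had 1 fall of 5, also 1 when adjusted over the list alone, in the minor arm miR-29a-5p (-0.29 log2; 0.776). Of 11 let-7 members let-7i-5p (0.19 log2) and miR-98-5p (0.16, 0.0436) rose, 1 of them when adjusted over the list alone (0.776), and miR-98-5p loses its call without any 1 of 18 arrays and with slide as a block (0.0595). In the smooth muscle and mesenchymal list miR-199a-3p rose and miR-199b-5p fell of 8, also 1 and 1 when adjusted over the list alone (0.776), with miR-143-3p at -0.05 log2. The miR-17 clusters had miR-20a-5p as the only rise of 12 and 0 when adjusted over the list alone (0.786).

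No member passed in the lists of striated muscle (4 members, such as miR-133a-3p at 0.20 log2), the miR-23-24-27 clusters (5), the Dlk1-Dio3 region (8, such as miR-136-5p at -0.32 log2) or viral controls (3 of 39 on the array tested), and 0 passed when adjusted over each list alone (camera of limma, adjusted p 0.776, 0.776, 0.776 and 0.912; 0 of these 4 lists passed with the estimated correlation). Of the lists too small for a list test, the erythroid miR-451 (0.06 log2) and miR-144-3p (-0.20) did not pass, nor did miR-122-5p of liver (1.02 ± 0.51, 0.139). miR-210-3p, a miRNA of hypoxia, fell by 0.20 ± 0.06 log2 (0.0157), and of the endothelial pair miR-126-5p was at -0.06 log2 beside the fall of miR-126-3p.

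After 4 weeks of smoke miR-135b-5p rose by 3.95 ± 0.15 log2 (4 smoke and 4 control arrays, limma adjusted p 3.48e-17), miR-146b-5p by 1.28 ± 0.08 (2.43-fold, 5.33e-13), miR-132-3p by 1.18 ± 0.17 and miR-21-5p by 0.97 ± 0.09 (1.95-fold, 6.53e-09). miR-193-3p fell by 1.48 ± 0.36 log2 (0.00546), miR-142-3p by 1.28 ± 0.34 and miR-142-5p by 1.06 ± 0.26. In all, 108 miRNAs changed, 77 higher and 31 lower, 13 of them by more than 1 log2, and 142 had an unadjusted p under 0.05. The split was 51 higher and 10 lower when scaled by all probes, 48 and 31 with quantile scaling, 4 and 0 with no scaling, 46 and 38 with the scanner's sum per miRNA and 57 and 39 in the deposited series table. The median over all miRNAs lay at 0.17 log2, against 0.064 log2 with the scaling by all probes and 0.067 with quantile scaling, and small rises depend on the scaling. miR-141-5p (0.19 log2), miR-24-3p (0.25) and miR-23a-3p (0.41) turn to -0.04, -0.14 and -0.0074 log2 with quantile scaling, and with slide as a block they do not pass (0.0607, 0.0587 and 0.0588). Without smoke array 3 the count is 37, without smoke array 2 it is 40 and without control array 4 it is 43. On the leading component smoke arrays 2 and 3 have the highest scores of all arrays (9.12 and 4.84) and control array 4 the lowest (-5.28), and without the 2 smoke arrays the count is 17 (17 higher, 0 lower). With a normexp background correction 46 changed, the median lay at -0.76 log2, and of 60 named calls 16 ended and another 16, all rises, turn negative without passing.

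Rises at 4 weeks that pass whichever single array is left out include miR-135a-1-3p (0.91 ± 0.17 log2, limma adjusted p 0.000544), miR-342-3p (0.86 ± 0.18), miR-155-5p (0.86 ± 0.21, 0.00571), miR-672-5p (0.84 ± 0.18), miR-139-3p (0.74 ± 0.14), miR-1904 (0.73 ± 0.19), miR-532-3p (0.72 ± 0.18) and miR-1224-5p (0.71 ± 0.15). So do those of the clustered miR-183-5p (0.65 ± 0.11 log2) and miR-182-5p (0.56 ± 0.13), of miR-31-5p (0.59 ± 0.09), miR-31-3p (0.50 ± 0.06), miR-34a-5p (0.57 ± 0.15), miR-98-5p (0.43 ± 0.11) and miR-429-3p (0.37 ± 0.07). Of these, miR-135a-1-3p, miR-155-5p, miR-672-5p, miR-139-3p, miR-1904, miR-532-3p, miR-183-5p, miR-182-5p, miR-31-5p and miR-31-3p turn to between -0.97 and -0.27 log2 with the normexp correction, without passing, around its median of -0.76. Of 60 named calls at 4 weeks 48 end without smoke arrays 2 and 3 and 48 when only the arrays of 4 weeks are fitted, and 10 pass in both. Those 10 are the 4 leading rises with miR-135a-1-3p, miR-139-3p, miR-183-5p, miR-31-5p, miR-31-3p and miR-429-3p, while miR-342-3p, miR-155-5p, miR-672-5p, miR-1904, miR-532-3p, miR-1224-5p and miR-98-5p pass in neither. Other rises end without smoke array 2: miR-223-3p (0.76 ± 0.28 log2; 0.62 without it, adjusted p 0.155), miR-342-5p (0.75 ± 0.23; 0.53, 0.108), miR-690 (0.71 ± 0.20; 0.53, 0.0828), miR-200c-3p (0.57 ± 0.17; 0.40, 0.109) and miR-146a-5p (0.48 ± 0.15; 0.37, 0.102). The same array carries much of the falls of miR-32-5p (-1.58 ± 0.44 log2; -1.05 without it, 0.0754), miR-144-3p (-1.31 ± 0.52; -0.77, 0.293), miR-29b-3p (-1.08 ± 0.38; -0.64, 0.211), miR-34b-5p (-0.81; -0.56, 0.151), miR-34c-5p (-0.64 ± 0.18; -0.47, 0.0754) and miR-210-3p (-0.39 ± 0.12; -0.18, 0.0828). Control array 4 carries those of miR-205-5p (-1.40 ± 0.48 log2; -0.92 without it, 0.13), miR-133a-5p (-1.33 ± 0.44; -0.92, 0.116), miR-133b-3p (-0.98 ± 0.37; -0.64, 0.185) and the muscle miRNA miR-133a-3p (-0.93 ± 0.36; -0.59, 0.201). With slide as a block neither miR-133a-3p (0.0508) nor miR-144-3p (0.0619) passes. Control array 1 carries that of miR-203-3p (-0.72 ± 0.24 log2; -0.42 without it, 0.127).

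miR-24-1-5p (-0.76 ± 0.18 log2, limma adjusted p 0.00474), miR-199b-5p (-0.53 ± 0.14, 0.00765) and miR-497-5p (-0.22 ± 0.07, 0.0238) also fell at 4 weeks. None of these falls passes without smoke arrays 2 and 3 or when only the arrays of 4 weeks are fitted, where 0 miRNAs are lower. With the normexp correction miR-199b-5p (-0.40 log2, 0.0921) and miR-497-5p (-0.063, 0.66) do not pass. The inflammation-responsive list had 8 of 9 members higher, also 8 when adjusted over the list alone (camera of limma, adjusted p 4.56e-08; with the estimated correlation 0.0396). Of 8 leukocyte members 5 rose and 2 fell, also 5 and 2 when adjusted over the list alone (0.823; 0.878), and of 14 epithelial members 7 rose and 2 fell, with 7 and 3 when adjusted over the list alone (0.823; 0.878). The striated muscle list had 3 of 4 members lower, also 3 when adjusted over the list alone, with an adjusted p of 0.0379 at the preset correlation and an adjusted p of 0.569 at the estimated one. Control arrays 1 and 4 of 4 weeks, and smoke array 3 of 8 weeks, are the arrays highest in the muscle miRNA miR-206-3p, with miR-133a-3p 1.63 ± 0.27 log2 over the other arrays of their groups. Without these 3 arrays 19 miRNAs changed at 4 weeks, 18 higher and 1 lower. In the let-7 list 5 of 11 rose and 6 when adjusted over the list alone (adjusted p 0.37; with the estimated correlation the adjusted p is 0.878). Of these let-7d-5p (0.43 log2), let-7a-5p (0.42), let-7f-5p (0.38) and let-7g-5p (0.25) each lose their call without control array 4, smoke array 2 or smoke array 3 and with quantile scaling, where they are at 0.17, 0.021, 0.14 and 0.048 log2, and let-7a-5p also with slide as a block (0.0567).

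Smoke for 6 weeks raised miR-135b-5p by 4.41 ± 0.15 log2 (4 smoke and 4 control arrays, limma adjusted p 2.46e-18), miR-146b-5p by 1.41 ± 0.08 and miR-21-5p by 1.29 ± 0.09. miR-34a-5p rose by 0.95 ± 0.15 log2 (9.24e-05), miR-449a-5p by 0.86 ± 0.18 (0.00203) and miR-132-3p by 0.83 ± 0.17 (0.00132). In all, 22 miRNAs changed, 21 higher and 1 lower, and 54 had an unadjusted p under 0.05. It was 12 higher and 4 lower when scaled by all probes and 14 and 9 with quantile scaling, 15 and 3 in the deposited series table, and turned to 10 and 13 with the scanner's sum per miRNA. After normexp background correction 4 changed and 15 of 19 named calls ended. miR-31-5p (0.54 ± 0.09 log2), miR-7a-5p (0.41 ± 0.10), miR-141-5p (0.40 ± 0.08), miR-185-5p (0.39 ± 0.08), miR-429-3p (0.37 ± 0.07) and miR-31-3p (0.37 ± 0.06) rose and pass whichever single array is left out.

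Smaller margins at 6 weeks belong to miR-672-5p (0.64 ± 0.18 log2; 0.55 without control array 1, limma adjusted p 0.093), miR-183-5p (0.40 ± 0.11; 0.35 without that array, 0.0729), miR-326-3p (0.42 ± 0.12; 0.33 without control array 3, 0.116), let-7i-5p (0.31 ± 0.08; 0.27 without that array, 0.0909) and miR-146a-5p (0.50 ± 0.15; 0.47 without smoke array 2, 0.0843; 0.0518 with slide as a block). The only fall, of let-7a-1-3p (-0.47 ± 0.13 log2, 0.024), is at -0.33 without control array 4 (0.123). miR-133a-3p was at 1.12 ± 0.36 log2 (0.0563). The inflammation-responsive list had 7 of 9 members higher and 8 when adjusted over the list alone (camera of limma, adjusted p 1e-14; with the estimated correlation 0.00139), and the epithelial list 3 of 14 higher and 4 when adjusted over the list alone (0.0855; 0.296).

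At 8 weeks miR-135b-5p rose by 4.10 ± 0.15 log2 (4 smoke and 4 control arrays, limma) and miR-21-5p by 1.08 ± 0.09 (2.12-fold). miR-135a-1-3p rose by 1.01 ± 0.17 log2 (adjusted p 0.000229), miR-146b-5p by 0.85 ± 0.08 (1.81-fold) and miR-132-3p by 0.78 ± 0.17 (0.00297). The count of changed miRNAs was 30, of which 10 were higher and 20 lower, and 65 had an unadjusted p under 0.05. Scaled by all probes the split was 20 and 23, and with no scaling 1 and 202 with a median of -0.86 log2 instead of -0.05. With the scanner's sum per miRNA it was 10 and 50, and 12 and 40 in the deposited series table. With a normexp background correction 3 changed, the median was 0.22 log2, and of 24 named calls 14 ended and 7 turned. Neither miR-146b-5p (0.033 log2) nor miR-21-5p (0.26) passes with no scaling. miR-132-3p, miR-1892 (0.75 ± 0.19 log2), miR-139-3p (0.57 ± 0.14), miR-1897-5p (0.53 ± 0.15) and miR-1895 (0.48 ± 0.11) turn to -0.04, -0.07, -0.25, -0.29 and -0.34 log2 with no scaling, which moves all miRNAs down and leaves these above the median. Without smoke array 4 miR-689_v15.0 (0.94 ± 0.26 log2) is at 0.73 (0.0644) and miR-1897-5p at 0.37 (0.0656).

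The falls at 8 weeks were led by miRNAs of the Sfmbt2 intron, although with a normexp background correction miR-669n (0.28 log2) and miR-467d-3p (0.26), like miR-30b-3p (0.27) and miR-204-5p (0.39), turn positive without passing, beside a median of all miRNAs of 0.22. miR-669n, above background on no smoke array and at least 1.51-fold higher in control, fell by 0.78 ± 0.16 log2 (4 and 4 arrays, limma adjusted p 0.00151), miR-669f-3p by 0.73 ± 0.12 (0.00012) and miR-467d-3p by 0.66 ± 0.16. Every smoke array of 8 weeks has weaker signal than every control array (75th percentiles 1229 to 1681 against 2337 to 3472). Fewer miRNAs were detected on them as well (226 to 247 against 253 to 291). Missing detection of miRNAs near the floor, such as miR-669n, therefore cannot be told apart from weaker signal at 8 weeks. miR-335-5p, from an intron of the imprinted gene Mest, fell by 0.57 ± 0.11 log2 (0.000616), miR-181c-5p by 0.43 ± 0.07 (0.00012), miR-181d-5p by 0.32 (0.00582), miR-497-5p by 0.41 ± 0.07 (0.000352) and miR-30b-3p by 0.36 ± 0.09. miR-195-5p (-0.40 ± 0.10 log2, 0.0079) and miR-100-5p (-0.44 ± 0.13) are at -0.31 (0.0531) and -0.36 (0.118) without smoke array 2, and miR-204-5p (-0.47 ± 0.15) is at -0.40 (0.145) without control array 1 and does not pass with slide as a block (0.0667). miR-34a-5p (0.34 ± 0.15 log2, 0.165), miR-146a-5p (0.08 ± 0.15), miR-31-3p (0.17 ± 0.06, 0.0692) and miR-31-5p (-0.01 ± 0.09) did not pass. The inflammation-responsive list had 4 of 9 members higher and 5 when adjusted over the list alone (camera of limma, adjusted p 8.75e-10; with the estimated correlation 0.0157), and the miR-15-16 list had 2 of 8 lower (0.414).

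By 12 weeks of smoke the rise of miR-135b-5p was 4.98 ± 0.16 log2 (3 smoke and 4 control arrays, limma adjusted p 8.49e-19; at least 26.3-fold). miR-449a-5p rose by 1.52 ± 0.20 log2 (2.87-fold, 3.38e-06), miR-21-5p by 1.44 ± 0.10 (2.71-fold) and miR-146b-5p by 1.42 ± 0.08 (2.68-fold). miR-34a-5p rose by 0.83 ± 0.16 log2 (0.000987), miR-132-3p by 0.74 ± 0.18 (0.00802), miR-146a-5p by 0.64 ± 0.16, miR-31-3p by 0.62 ± 0.07 (9.21e-08), miR-31-5p by 0.52 ± 0.10, miR-141-5p by 0.36 ± 0.08 and miR-429-3p by 0.32 ± 0.07. In all, 26 miRNAs changed, 14 higher and 12 lower, and 70 had an unadjusted p under 0.05. The split was 19 and 9 when scaled by all probes, with a median of 0.041 log2 instead of -0.075, and 5 and 0 with no scaling, with a median of 0.20. In the deposited series table it was 16 and 31. miR-192-5p (0.73 ± 0.22 log2, 0.0348) is at 0.17 log2 without smoke array 3 (0.12). On that array the liver miRNA miR-122-5p lies at 1.57 log2, against at most -4.70 log2 on any other.

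miR-455-3p fell by 0.93 ± 0.21 log2 at 12 weeks (3 smoke and 4 control arrays, limma adjusted p 0.00453), miR-466b-3p by 0.73 ± 0.15, miR-467d-3p by 0.70 ± 0.17 and miR-669f-3p by 0.63 ± 0.13. miR-195-5p (-0.47 ± 0.11 log2), miR-497-5p (-0.44 ± 0.08) and miR-181c-5p (-0.28, 0.0181) fell, as they had at 8 weeks. Without smoke array 2 miR-30d-5p (-0.28 ± 0.09 log2, 0.0484) is at -0.24 (0.231) and miR-126-3p (-0.25 ± 0.07, 0.0315) at -0.23 (0.133), with slide as a block they do not pass (0.0644 and 0.0526), and with no scaling they turn to 0.04 and 0.07, below its median of 0.20. miR-494-3p (0.49 ± 0.13 log2) is at 0.40 (0.152) without smoke array 1, and miR-188-5p (0.27 ± 0.08, above background on no control array, at least 1.01-fold) at 0.20 (0.14) without smoke array 3. With a normexp background correction miR-188-5p (-0.18 log2) and miR-141-5p (-0.0060) turn negative at 12 weeks without passing, 19 of 25 named calls ended, the count is 4 and the median -0.18 log2. The inflammation-responsive list had 7 of 9 members higher, also 7 when adjusted over the list alone (camera of limma, adjusted p 1.92e-16; with the estimated correlation 0.000638), the epithelial list 2 of 14 and 4 when adjusted over the list alone (0.0547; 0.149), and the p53 list 2 of 7, miR-34a-5p and miR-192-5p (0.0776; 0.148).

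**Figure D3:**
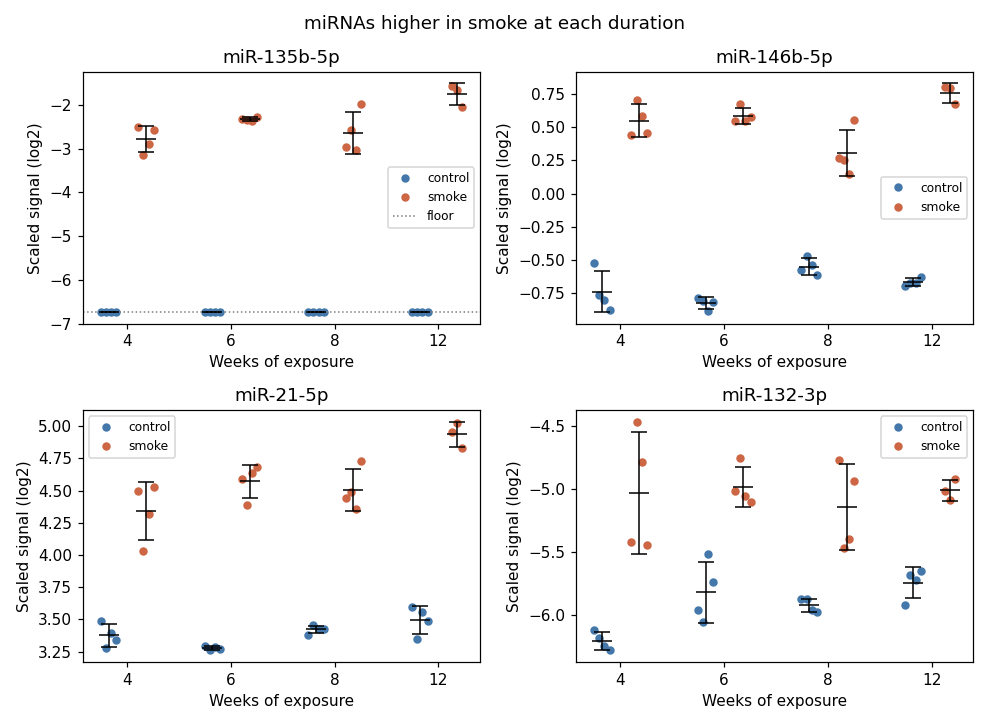
Scaled signal (log2, vertical) against weeks (horizontal) of miR-135b-5p, miR-146b-5p, miR-21-5p and miR-132-3p, with control in blue and smoke in orange, points for arrays and bars for mean and SD. The smoke minus control difference of miR-135b-5p is 3.95, 4.41, 4.10 and 4.98 log2 at 4, 6, 8 and 12 weeks against control arrays at the floor (dotted).

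Of the rises at 6 weeks, 15 were also rises at 4 weeks (5.92 by chance from the numbers called) and 11 were also rises at 12 weeks (1.08 by chance), and of the falls at 8 weeks 7 were also falls at 12 weeks (0.879 by chance). Of the falls at 4 weeks 2 were also falls at 8 weeks (2.27 by chance) and 2 at 12 weeks (1.36 by chance), and none was the fall at 6 weeks. Across the 273 miRNAs the differences at 6 and 12 weeks correlate with r 0.81, at 6 and 8 weeks with r 0.72 and at 4 and 6 weeks with r 0.48. Each r includes miR-135b-5p, which at 3.95 to 4.98 log2 lies far from all other miRNAs, and was not computed without it. How alike the durations are over the other miRNAs is therefore not shown by r. No miRNA passed in opposite directions. Rises at 3 durations were those of miR-141-5p, miR-146a-5p, miR-31-3p, miR-31-5p, miR-34a-5p and miR-429-3p, and falls at 3 those of miR-497-5p and miR-669f-3p, with no fall at all 4. Both of these falls count 4 weeks, where 0 miRNAs are lower without smoke arrays 2 and 3 of 4 weeks.

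The smoke effect differed between durations for 20 miRNAs, against 96 at an unadjusted p under 0.05. Leaving out 1 array moves this count to between 10 (without control array 4 of 4 weeks) and 67 (without smoke array 4 of 8 weeks). With a normexp background correction 0 remain in the limma fit and all 10 miRNAs named here lose their call (adjusted p 0.2 to 0.8). The count is 7 with a variance trend and robust moderation and 133 with no scaling. miR-449a-5p (moderated F 12.7, 31 arrays, limma adjusted p 0.00635) had effects of -0.09, 0.86, 0.39 and 1.52 log2 at 4, 6, 8 and 12 weeks, and miR-146b-5p (F 12.1, 0.00635) of 1.28, 1.41, 0.85 and 1.42. miR-31-5p (F 9.74, 0.0178) had 0.59, 0.54, -0.01 and 0.52 log2 and miR-31-3p (F 9.03, 0.0178) 0.50, 0.37, 0.17 and 0.62, with the smallest effect of both arms at 8 weeks. miR-1895 (F 9.15, 0.0178) was at 0.48 log2 at 8 weeks and between -0.31 and -0.02 at the others, and miR-335-5p (F 8.71, 0.0185) at -0.57 log2 at 8 weeks and between -0.03 and 0.13 at the others.

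miR-135b-5p differed with F 8.45 (limma adjusted p 0.0192), miR-195-5p with F 8.08 (0.0218; 0.16, -0.10, -0.40 and -0.47 log2), miR-181c-5p with F 7.77 (0.0231; 0.00, -0.07, -0.43 and -0.28) and miR-22-5p with F 7.63 (0.0231; 0.34, 0.16, -0.22 and 0.00). The control means of miR-135b-5p have a range of 0 at the floor, so its F compares smoke levels alone. Its control values without spread also make this F larger. The difference of miR-135b-5p ends without smoke array 1 of 12 weeks (F 6.08, adjusted p 0.06), that of miR-195-5p without control array 4 of 4 weeks (F 6.62, 0.0518), and those of miR-181c-5p and miR-22-5p without smoke array 2 of 8 weeks. When scaled by all probes miR-449a-5p, miR-146b-5p, both arms of miR-31, miR-335-5p, miR-195-5p, miR-181c-5p and miR-22-5p no longer pass this test.

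Among control mice 19 miRNAs differed between durations, against 84 at an unadjusted p under 0.05. The count is 84 when scaled by all probes, 151 with no scaling and 3 with a normexp background correction, which ends 8 of the 10 calls named here, all but those of miR-29a-3p and miR-133a-3p. The collagen-repressing miR-29a-3p had control means of 2.97, 3.18, 3.23 and 3.47 log2 at 4, 6, 8 and 12 weeks (moderated F 14.9, 16 control arrays, limma adjusted p 0.00214), and miR-449a-5p of -2.61, -3.18, -2.96 and -3.77 (F 14.0, 0.00214). miR-1895 had means of -4.26, -4.07, -4.42 and -3.78 log2 (F 12.4, 0.00355). miR-133a-3p of muscle (F 8.77; -1.66, -3.50, -2.52 and -2.57 log2) and miR-1224-5p (F 8.95; -1.51, -1.03, -1.20 and -0.74) do not pass without control array 4 of 4 weeks (F 6.72 and 6.62, 0.0569 each). miR-450a-5p (F 9.18; -2.54, -2.70, -2.62 and -2.90 log2) is at F 6.45 (0.0542) without control array 1 of 12 weeks, and miR-31-5p (F 8.91; -3.44, -3.43, -3.04 and -3.35) at F 6.14 (0.0602) without control array 3 of 8 weeks. The remaining 3 of the 10 with the lowest p are miR-872-3p (F 8.72), miR-379-5p (F 8.57) and miR-669n (F 8.55), each with an adjusted p of 0.0124. miR-872-3p (0.0512) and miR-379-5p (0.058) do not pass without control array 4 of 4 weeks, nor miR-669n without control array 1 (0.07) or 3 (0.0602) of 8 weeks. Without control array 4 of 4 weeks 7 of the 19 remain.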

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

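The tests of the covariates, of heart muscle, of moved control levels and of multiciliated cells were chosen only after the result was seen.

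Of 196 sets of replicate values checked, 7 hold 1 array far from the others of its group, where 9.8 would be reached by chance. In 6 weeks smoke, array 2 has a striated muscle list mean of -4.20 log2, with the others between -3.74 and -3.72. In 4 weeks control, array 4 has a miR-30 list mean of 6e-04 log2, with the others between 0.17 and 0.20. In 8 weeks control, array 2 has a miR-29 list mean of 0.0015 log2, with the others between -0.12 and -0.10. The miR-15-16 list mean is -0.39 log2 on array 4 of 4 weeks control and 0.029 log2 on array 2 of 6 weeks smoke, with the others of both groups between -0.19 and -0.16. The p53 list mean is -2.00 log2 on array 4 of 6 weeks smoke, with the others between -2.06 and -2.05. miR-429-3p is at -0.93 log2 on array 1 of 12 weeks control, with the others between -0.83 and -0.82.

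A smoke effect that differs between durations was seen by moderated F test of limma for miR-449a-5p (F 12.7), miR-146b-5p (12.1), miR-31-5p (9.74), miR-1895 (9.15), miR-31-3p (9.03), miR-335-5p (8.71), miR-135b-5p (8.45), miR-195-5p (8.08), miR-181c-5p (7.77) and miR-22-5p (7.63). Control levels that moved between durations are a possible explanation, but among the 20 miRNAs past the test the control means range wider than the smoke means in 8, a share too near to even for the test to tell. The control test also passed for 5 of them: miR-449a-5p (control means over 1.16 log2, smoke means over 0.44), miR-1895 (0.64 and 0.34), miR-31-5p (0.40 and 0.215), miR-335-5p (0.53 and 0.52) and miR-135a-1-3p (0.69 and 0.46). miR-135b-5p and miR-721 have control means with a range of 0 and could not count among the 8. For miR-449a-5p a separate test of its control range met the prediction, so moved control levels are a candidate explanation there. A changed share of multiciliated cells could also lie behind miR-449a-5p, whose effect is 1.61 ± 0.27 log2 larger at 12 than at 4 weeks. The same difference is 1.23 log2 for miR-34b-5p and 0.91 for miR-34c-5p but -0.56 for miR-34b-3p and -0.44 for miR-34c-3p (median 0.234), so the test cannot tell.

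The high count at 4 weeks goes with a leading component of the deviations from the group means that carries 63.0% of that variance, with miR-144-3p, miR-29b-3p and miR-141-3p at its negative end and, at its positive end, the herpesvirus control mghv-miR-M1-2-3p ahead of miR-342-5p and miR-139-5p. An axis of variation shared by the arrays is a candidate explanation for part of the calls, since with the score as a covariate 29 of the 108 miRNAs stay called. The score is made from the same miRNA values, with the group differences left in. As a covariate it would also remove a smoke effect along the axis, so this loss of calls cannot tell the causes apart. Weaker overall signal goes with that score (r -0.781 with the array's 75th percentile, 31 arrays, permutation adjusted p 9e-05; rho -0.824, and r -0.746 without the 2 farthest arrays). With the percentile as a covariate all 108 stay called. This cannot tell whether weaker signal is the whole cause, since smoke and control arrays at 4 weeks have nearly the same mean percentile. Their log2 values run from 10.23 to 11.25 and from 10.43 to 11.49, so a linear covariate can barely move the smoke effect. Hybridisation differences are unlikely behind the axis within groups (r -0.00681 to the hybridisation spike-ins), which leaves open the -0.33 and -0.25 log2 of these spike-ins between smoke and control at 4 weeks.

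Chance was tested by regrouping arrays. At 4, 6, 8 and 12 weeks only 1 of 35 splits of the arrays, the real one, gave as many miRNAs (108, 22, 30 and 26, with at most 58, 0, 4 and 7 in any other). These splits ignore slide, although smoke and control arrays of the same slide correlate (mean r 0.233 against -0.076 for other pairs). In 100 draws that reassign smoke and control within each duration only the real one gave 76, with at most 56 in any other, and in 100 draws of durations only the real one gave 20, with at most 1 in any other. For control mice the real grouping alone gave 19, but another of the 100 gave 18. As many lists as the 1 called came up in 77 of 100 draws (at most 5), so chance cannot be excluded for the number of lists. In a test chosen only after that, 31 of 99 other draws called the inflammation-responsive list, with a smallest camera p of any list of 7.81e-10 against 2.25e-14 for the real grouping.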

How the results depend on the processing

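Both covariates, both sets of arrays left out together and the correction on the median signal are tests chosen only after the result was seen.

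miR-135b-5p, miR-146b-5p and miR-21-5p kept their direction in every alternative with a value, and the inflammation-responsive list was called in every alternative in which the lists were tested, which leaves out the fits on the groups' own arrays. Counts not given here stayed within 1.5 times. Where a count moved, the cause was not tested, except that fewer arrays or other sets of miRNAs are part of the alternative itself. The number of arrays limits the precision, and miRNAs near the floor (30.3% to 39.8% of spots per array are above background) have less certain values. The normexp correction of the mean signal was not run because that column is absent. With the higher floor, miRNAs at the floor on all arrays have no value.

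Scaled by all probes, 61 miRNAs changed at 4 weeks and 84 differed among controls. With quantile scaling 46 changed at 8 weeks and 43 at 12. With no scaling the counts were 4, 2, 203 and 5 at 4, 6, 8 and 12 weeks, 29 averaged, 133 for a differing effect and 151 for controls. The scanner's sum gave 60 at 8 weeks. Without a filter 55 changed at 4 weeks, 12 had a differing effect, 12 differed among controls and 3 lists were called. With detection on all arrays 12 differed among controls. The higher floor gave 63, 13, 18 and 15 at the durations, 45 averaged, 10 for a differing effect and 11 for controls, and miR-132-3p no longer passed averaged. The deposited series table gave 52 at 8 weeks, 47 at 12, 46 for a differing effect and 35 for controls. Robust moderation with a trend gave 7 for a differing effect. Fitted on their own groups, 18 changed at 4 weeks and 93 at 12, and 93 differed among controls.

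The normexp correction of the median signal gave 46, 4, 3 and 4 at the durations, 12 averaged, 0 for a differing effect (limma) and 3 for controls. Of 211 named values 110 lost their call under it, 0 gained one and 31 changed sign, none of those passing. Those at 4 weeks are miR-132-3p (-0.72), miR-135a-1-3p (-0.78), miR-155-5p (-0.38), miR-672-5p (-0.62), miR-342-5p (-0.86), miR-139-3p (-0.88), miR-1904 (-0.65), miR-532-3p (-0.76), miR-690 (-0.25), miR-31-3p (-0.87), miR-31-5p (-0.27), miR-141-5p (-0.97), miR-182-5p (-0.97), miR-183-5p (-0.46), miR-200b-5p (-0.91) and miR-494-3p (-0.78). At 8 weeks they are miR-669n (0.28), miR-467d-3p (0.26), miR-466b-3p (0.39), miR-186-3p (0.36), miR-204-5p (0.39), miR-669a_v15.0 (0.42) and miR-30b-3p (0.27), and at 12 weeks miR-141-5p (-0.0060) and miR-188-5p (-0.18). Averaged they are miR-139-3p (-0.059), miR-1897-5p (-0.046), miR-31-3p (-0.041), miR-141-5p (-0.091), miR-182-5p (-0.10) and miR-194-5p (-0.022). The cause was not tested. Without smoke arrays 2 and 3 of 4 weeks the count was 17 at 4 weeks, 46 at 12 and 66 for controls. Without the 3 arrays with raised muscle miRNAs it was 19 at 4 weeks and 9 for a differing effect. With the component score as a covariate the counts were 45, 74, 99 and 99, with 143 averaged, 73 for a differing effect, 102 for controls and 2 lists. The 75th percentile as a covariate gave 44 at 6 weeks, 121 at 8, 41 at 12, 167 for a differing effect and 130 for controls.

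Reversed values at 4 weeks were those of miR-141-5p (-0.035 log2), miR-23a-3p (-0.0074) and miR-24-3p (-0.14) with quantile scaling, miR-141-5p (-0.046) in the deposited series table, miR-203-3p (0.012) without the arrays with raised muscle miRNAs, and miR-144-3p (0.060) and miR-23a-3p (-0.0083) with the component covariate. With no scaling miR-132-3p (-0.038), miR-1892 (-0.070), miR-139-3p (-0.25), miR-1897-5p (-0.29) and miR-1895 (-0.34) reversed at 8 weeks, miR-30d-5p (0.038) and miR-126-3p (0.069) at 12 weeks, and miR-199a-3p (-0.020) and miR-20a-5p (-0.0095) averaged. With no scaling the median of all miRNAs moves to -0.86 log2 at 8 weeks, 0.20 at 12 and -0.15 averaged. Signs there turn with that shift. With the normexp correction the median moves to -0.76 at 4 weeks, 0.22 at 8, -0.18 at 12 and -0.14 averaged. That shift is not common to all miRNAs: at 4 weeks miR-141-5p goes from 0.19 to -0.97 log2, but miR-199a-3p from 0.22 to 0.40. The cause was not tested further.

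Calls of named values ended, with the direction kept, in 62 cases when scaled by all probes, 30 with quantile scaling, 128 with no scaling, 42 with the scanner's sum, 10 with the mean of all probes, 47 without a filter, 6 with detection on all arrays, 29 with the higher floor, 28 in the deposited series table, 8 with robust moderation, 64 when fitted on their own groups, 17 with the replicate block and 18 with the slide block. With each array left out in turn the counts ranged from 37 to 150 at 4 weeks, 15 to 25 at 6, 22 to 41 at 8, 18 to 28 at 12, 70 to 91 averaged, 10 to 67 for a differing effect and 7 to 25 for controls, and no named value reversed. With the replicate block the counts were 90, 22, 28, 22, 71, 15 and 16, and with slide as the block 87, 21, 28, 23, 73, 16 and 16. The replicate numbers were not taken to pair smoke and control samples, since 9 of 15 same-number pairs correlate over 0.1 (lowest -0.467; mean r 0.126 against -0.040 for other pairs) and 7 of 15 smoke arrays correlate best with their own number. At 4 weeks all 4 same-number pairs correlate over 0.1 (lowest 0.115). Number and slide coincide in the pairs of 4, 6 and 8 weeks. At 12 weeks same-number pairs lie on different slides and correlate with r 0.17, -0.42 and -0.47. The replicate and slide blocks are therefore nearly the same alternative. Pairs on the same slide correlate with a mean r of 0.233 and others with -0.076.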

Other observations

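The test of the Sfmbt2 families and that of heart muscle were chosen only after the result was seen.

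The miR-297, miR-466, miR-467 and miR-669 families are transcribed from an intron of the gene Sfmbt2 in rodents, and their near-identical sequences may share probes: of 12 tested members 6 fell and none rose averaged over the durations (median -0.21 log2, -0.44 at 8 weeks). Those that fell are miR-466b-3p, miR-467b-5p (-0.23 log2), miR-467d-3p, miR-669a_v15.0 (-0.25), miR-669f-3p and miR-669n (-0.28). By duration 1, 0, 5 and 4 fell at 4, 6, 8 and 12 weeks, but with the scaling by all probes, quantile scaling and no scaling 9, 10 and 12 fell at 8 weeks and 2, 4 and 0 at 12 weeks. At 8 weeks every smoke array also has weaker signal than every control array. As a group they passed at the preset correlation (camera of limma, 15 and 16 arrays, p 0.000141) but not at the estimated correlation of 0.386 (p 0.0842). By duration the unadjusted camera p at the estimated correlation is 0.364, 0.262, 0.0459 and 0.235 at 4, 6, 8 and 12 weeks. Averaged, 6 fell with the scaling by all probes, 6 with quantile scaling and 5 with no scaling, but with the normexp background correction 0. Under that correction their median at 8 weeks is 0.40 log2, where that of all miRNAs is 0.22, and miR-466b-3p (0.39), miR-467d-3p (0.26), miR-669a_v15.0 (0.42) and miR-669n (0.28) turn positive without passing.

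Both miR-181c-5p (-0.19 log2 averaged) and miR-181d-5p (-0.13), 2 products of 1 cluster, fell, as did miR-181a-1-3p (-0.29) from another locus. Between smoke and control arrays the 2 hybridisation spike-ins differ by -0.33 and -0.25 log2 at 4 weeks, 0.0078 and -0.0075 at 6, -0.11 and -0.10 at 8 and 0.13 and 0.11 at 12 weeks. The 2 labelling spike-ins differ by 0.16 and 0.21 log2 at 4 weeks, 0.18 and 0.22 at 6, 0.04 and 0.13 at 8 and 0.38 and 0.40 at 12 weeks.

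Tissue-restricted miRNAs are high on single arrays. On array 3 of 12 weeks smoke miR-122-5p is at 1.57 log2 (-4.70 at most elsewhere), miR-192-5p at -1.60 (-3.24) and miR-194-5p at -2.78 (-3.63). RNA of liver is a candidate explanation, but 0 of its other listed miRNAs were measured on that array, so the test cannot tell. On arrays 1 and 4 of 4 weeks control and array 3 of 8 weeks smoke miR-1a-3p is 1.79 log2 over the other arrays of their groups, miR-133b-3p 1.69 and miR-203-3p 1.13. miR-206-3p, above background on 1 of the other 28 arrays, is at -3.30 log2 or more on these 3 and at most at -4.45 elsewhere, so its distance is bounded only from below. As a test of heart muscle, miR-208b-3p is only 0.31 ± 0.11 log2 higher there against 1.63 ± 0.27 log2 for miR-133a-3p. This cannot exclude heart muscle. miR-208b-3p is above background on 27 of the other 28 arrays and reaches -4.74 log2 among them, against at most -5.03 on these 3.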
